A study of Homo sapiens with 15 samples.

How the data were processed

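RNA from primary human hepatocytes was hybridised, per the labels' protocols, as biotin-labelled cRNA from 6 µg of total RNA to Affymetrix single-channel arrays. The labels give 5 groups of 3 arrays: untreated cells, and cells given 10 U/mL of IFN-α, or 25 ng/mL of IL28B, for 6 or 24 h. The protocol text also names a 12 h time, which is not analysed here. The deposited table holds log2 values for 54675 probe sets on 15 arrays. Per the submitters' processing notes, the authors made them with RMA (background correction, normalization between arrays and summary per probe set) and Partek, with versions not given in the sources used here. The values were used as deposited. Arrays have no read depth, so the number of arrays per group, 3, limits the precision. The 3' minus 5' difference of the control probe sets lay between 4.77 and 5.91 log2 units for ACTB and between 0.861 and 1.35 for GAPDH.

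Probe sets were named from the platform's gene table. Of them, 41097 had exactly 1 gene symbol, 1801 had several and 11777 had none. Entrez numbers were looked up in a RefSeq gene table (assembly GRCh38.p14), which matched 41043 probe sets and changed no symbol. Its start positions were also used for which genes neighbour each other, taken as adjacent tested genes on a chromosome. Affymetrix controls, XIST and Y-linked genes (106 probe sets) were left out. Each gene was represented by its single-symbol probe set with the highest mean over all arrays, which gave 19721 genes without a filter on dim genes. Where a gene named by the rule below had other probe sets, these were compared with it, except for the interaction. Values of genes named outside that rule had no such check. Of 331 called values of named genes, 170 had another probe set, which was called in the same direction in 118 and not called in 52, and none was called in the opposite direction. Named genes of which only some other probe sets were called in at least 1 comparison included RIGI, SOCS1, JAK2, GBP1, MAP1B, TOP2A, TYMS, AURKA, TFEC, PLCE1, SLC25A42, SESN3, CASP1 and IFNAR1.

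Each gene was fitted with limma (version 3.58.1, R version 4.3.3) over all 15 arrays, with a mean per group and empirical Bayes moderation. Contrasts covered each agent and time against untreated, IFN-α against IL28B at 6 and at 24 h, 24 against 6 h for each agent, and the agent by time interaction. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes were called at an adjusted p under 0.05. Log2 fold changes are given with limma's moderated SE, and group means with their SD.

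Gene lists were written before the data were examined, as were the design, the rule for named genes and most alternatives. There were 30 lists with 530 entries, of which 480 were measured. They cover interferon-stimulated and antigen presentation genes, chemokines, cell death, liver functions, cell cycle, stress and the markers of other liver and blood cells. Lists were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation, adjusted over the lists of each comparison. List members were also adjusted over the list alone. Lists of hypoxia targets and of myeloid interferon-responsive genes were added after the results were seen. Their p-values were adjusted over the added lists alone in each comparison, a milder adjustment than that over the 30 fixed lists.

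Named genes in each comparison with untreated were the 10 largest increases and the 5 largest decreases among called genes whose treated arrays all lay beyond all untreated arrays. To these came the 3 largest changes of each list discussed, and always IFNLR1, IL10RB, IFNAR1, IFNAR2, IRF9, USP18, SOCS1, CXCL9, CXCL10, CXCL11, IFNL1 and 1 gene that is not reported here. The other comparisons took the 5 largest changes in each direction. Genes named outside this rule are said to be chosen after their values were seen.

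The overlap of comparisons that share the untreated arrays was set against independent lists, and against unchanged groups simulated with the same controls (100 draws). The fit was tested on simulated data, with 200 of 19721 genes changed in the comparison of IFN-α at 6 h with untreated cells. It recovered 46.6% of changes of 0.5 log2 units, 92.5% of changes of 1 and 99.7% of changes of 2, with 5.80% false among the calls and 0 calls without a change. Camera called 4% of lists of randomly drawn genes at an unadjusted p under 0.05. Since the simulated genes were independent, that rate says nothing on lists of correlated genes. For the same reason, the recovered and false shares may not hold for the real arrays. There, the main axis of variation within groups, taken from the 9503 brighter genes outside the fixed lists, carried 54.6% of that variation in those genes.

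Alternatives were the replicate number as a block, the mean of a gene's probe sets, probe sets tested one by one, probe sets ending in _x_at or _s_at left out, the dimmer genes left out, arrays centred on their medians, quantile normalization, a fit of the compared groups alone, a trended robust prior, array weights, and each array left out in turn. A further 2 were chosen after the data were seen: leaving out the 2 arrays that stood apart, and a covariate for the array score on the main axis of variation within groups. Other splits of the arrays were counted for each comparison. Probe sets without a single symbol were counted but not used in the comparisons.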

Results

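Messenger RNA levels were measured on 15 single-channel oligonucleotide arrays in primary human hepatocytes, the parenchymal cells of the liver, kept in culture. The cells were left untreated, received IFN-α (a type I interferon) at 10 U/mL, or received IL28B (a type III interferon, also called interferon lambda 3) at 25 ng/mL. Treated cells were collected after 6 or 24 h, which gave 5 groups of 3 arrays. No collection time is stated for the untreated cells, so time in culture was not separated from treatment in any comparison with them. The deposited log2 values cover 54675 probe sets, of which 19721 genes were tested. The array medians lay between 5.31 and 5.38. The arrays of 1 group correlated with each other at r from 0.994 to 0.998 across probe sets, which are not independent replicates. IFN-α 24 h replicate 2 and IL28B 24 h replicate 3 stood apart on the main axis of variation within groups, with scores of 1.72 and 1.90 against -1.35 to 1.02 for the other 13 arrays. That axis, taken from the 9503 brighter genes outside the fixed gene lists, carried 54.6% of the variation within groups in those genes. The labels do not say whether the arrays of a group came from separate cultures or donors, so the p-values measure only the spread between these arrays. The number of arrays, 3 per group, limits the precision of each value.

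The first question was which genes hepatocytes changed under a type I interferon. After 6 h of IFN-α, the chemokine gene CXCL10 rose by 7.95 ± 0.15 (log2 fold change ± SE, n = 3 arrays per group, adjusted p = 2.96e-14), from 3.98 ± 0.34 (SD) in untreated cells. The antiviral genes IFI44L and RSAD2 rose by 7.12 ± 0.16 and 6.54 ± 0.0941 (adjusted p = 1.80e-13 and 2.34e-15). The chemokine gene CCL8 rose by 4.94 ± 0.14, EPSTI1 by 4.71 ± 0.11 and IFIT1 by 4.64 ± 0.0919 (adjusted p of at most 3.02e-12). IFI44, OASL, CMPK2 and MX2 completed the 10 largest increases, at 4.52, 4.52, 4.33 and 4.25. IFI44L, OR52K3P, AIM2, MX2, CXCL10, CXCL11 and CIITA lay low in untreated cells, from the 8.23 percentile of all genes for IFI44L to the 19.2 for CIITA, so their fold changes against untreated cells, here and below, are not exact. The largest decrease was in GPATCH11, which fell by 1.98 ± 0.11 (adjusted p = 7.27e-09). Its other probe set gave -0.18 and was not called. APPL2 fell by 1.005, SLC25A42 by 0.82 and SLC60A1 by 0.82 (adjusted p of at most 0.00516), and the 3 other probe sets of SLC60A1 were not called. GREM1 fell by 0.90 (adjusted p = 0.0117), a call lost without untreated replicate 3 (0.0647) or IFN-α 6 h replicate 2 (0.0668), and its other probe set was not called. IFN-α at 6 h changed 596 genes, of which 502 rose and 94 fell, with 183 and 2 of them by 2-fold or more. The count lay between 448 and 694 when single arrays were left out, and came to 1016 with the axis score as a covariate and 1759 with array weights. The share of higher genes was 84.2%, or from 56.3% with array weights to 91.2% without untreated replicate 1 or IFN-α 6 h replicate 3.

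**Figure D1:**
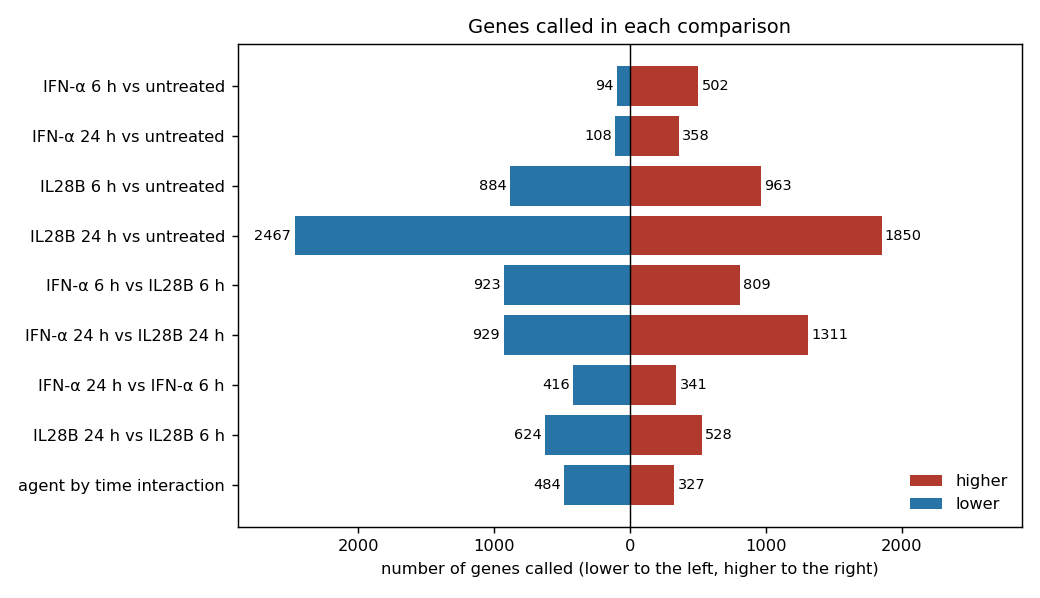
Number of genes called at an adjusted p under 0.05 in each comparison, with higher genes to the right of 0 and lower genes to the left, from a fit of all 15 arrays. In the interaction, higher means that the change from 6 to 24 h was more positive with IFN-α than with IL28B; IL28B at 24 h had the most calls, with 1850 higher and 2467 lower.

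Among the gene lists fixed before the data were examined, the antiviral effectors rose after 6 h of IFN-α in 44 of 46 members (45 adjusted over the list alone), with a list median of 2.49 (adjusted p = 3.69e-173). All 4 measured genes of ISG15 conjugation rose (4 adjusted over the list alone), among them HERC5 by 4.11, USP18 by 4.04 and ISG15 by 3.70, with a median of 3.87. Of the nucleic acid sensors, 8 of 15 rose (10 adjusted over the list alone), with AIM2 at 3.50, RIGI at 2.84 and IFIH1 at 2.62. Of the genes with gamma-activated elements and the guanylate-binding proteins, 14 of 17 rose (14 adjusted over the list alone), with GBP4 at 3.56, CIITA at 1.56 and GBP1 at 1.42. The other 2 probe sets of CIITA were not called. Chemokines rose in 6 of 22 cases (7 adjusted over the list alone, median 0.31), with CXCL11 at 3.08 (0.616 on its other probe set) beside CXCL10 and CCL8. CXCL9 rose by 0.83 (adjusted p = 0.00984, or 0.0668 without IFN-α 6 h replicate 1 and 0.0633 in a fit of the compared groups alone). Class I antigen presentation rose in 7 of 19 genes (12 adjusted over the list alone, median 0.31), with NLRC5 at 2.35, TAP1 at 2.15 and PSMB9 at 1.85. Cell death genes rose in 7 of 18 cases (10 adjusted over the list alone), with MLKL at 2.63, TNFSF10 at 2.001 and CASP1 at 0.95. Of the interferon regulatory factors, 3 of 7 rose (4 adjusted over the list alone), with IRF7 at 2.30 and IRF1 at 1.11. IRF9 rose by 1.53 and the feedback inhibitor SOCS1 by 0.85 (adjusted p = 0.00216). Class II antigen genes rose in 3 of 11 cases (4 adjusted over the list alone, median 0.30, adjusted p = 0.0267 with an estimated correlation), with HLA-DPA1 at 0.75, whose 2 other probe sets were not called.

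After 6 h of IFN-α, drug and bile acid metabolism had a median of -0.19 (adjusted p = 7.67e-06, or 0.148 with an estimated correlation), with 1 of 24 fallen and 11 adjusted over the list alone. CYP7A1 at -1.07 ± 0.32 and CYP2A6 at -0.75 ± 0.20 did not pass (adjusted p = 0.113 and 0.0602). No hepatic transporter changed (1 fell adjusted over the list alone), and that list's median of -0.18 passed only with the preset correlation (adjusted p = 0.00276, or 0.186 with an estimated correlation). The same held for interferon receptors and JAK-STAT genes (median 0.0878, 2 of 11 rose, 3 adjusted over the list alone, adjusted p = 0.0997 with an estimated correlation) and for negative regulators of interferon signalling (median 0.0661, 2 of 12 rose, 2 adjusted over the list alone, 0.0997). It also held for NF-κB targets (median 0.0276, 3 of 18 rose, 4 adjusted over the list alone, 0.0648), with IL15 at 1.24 and TLR2 at 0.57. Macrophage markers had a median of 0.13 (2 of 15 rose, 3 adjusted over the list alone, adjusted p = 0.111 with an estimated correlation), with VSIG4 at 0.39. Cholangiocyte markers had a median of 0.36 (1 of 7 rose, 4 adjusted over the list alone, 0.0648). The receptor genes IFNLR1, IL10RB, IFNAR1 and IFNAR2 gave 0.50, -0.065, -0.16 and -0.0199, and none was called.

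After 24 h of IFN-α, IFI44L rose by 5.84 ± 0.16 and RSAD2 by 4.99 ± 0.0941 (log2 ± SE, n = 3 arrays per group, adjusted p = 3.90e-12 and 1.15e-13), above untreated levels of 3.12 ± 0.40 (SD) for IFI44L. ISG15, IFI27 and IFITM1 rose by 3.69, 3.64 and 3.59, and CXCL10 by 3.13 ± 0.15 (adjusted p = 2.57e-09). The other members of the 10 largest increases were IFI44, IFIT1, OAS3 and MX2, at 3.37, 3.35, 3.23 and 3.20. CXCL11, CXCL9 and SOCS1, at 0.44 ± 0.21, 0.0258 ± 0.17 and 0.0693 ± 0.14, were not called. KCNAB1 fell by 1.30 ± 0.14, FABP4 by 1.13 ± 0.16 and the noncoding RNA DANCR fell by 1.002 ± 0.0874 (adjusted p of at most 8.85e-04), but the other probe sets of KCNAB1 and FABP4 were not called. SESN3 and GYS2 fell by 0.98 and 0.89 (adjusted p = 0.0209 and 0.0242), and leaving out any untreated array or IFN-α 24 h replicate 2 ended both calls (0.0617 to 0.112), as did IFN-α 24 h replicate 1 for GYS2 (0.0835) and the axis score as a covariate for both (0.136 and 0.141). In all, 466 genes changed (358 rose and 108 fell), with 63 and 3 of them by 2-fold or more. That count fell to 266, 209 and 218 without untreated replicates 1, 2 and 3, to 281 and 220 without IFN-α 24 h replicates 1 and 2, to 266 without the 2 arrays that stood apart, to 271 in a fit of the compared groups alone and to 274 with the axis score as a covariate, and came to 786 without the dimmer genes. The share of higher genes was 76.8%, or from 57.8% with array weights, which called 3421 genes, to 86.2% without untreated replicate 3.

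Antiviral effectors rose at 24 h of IFN-α in 38 of 46 cases (45 adjusted over the list alone), with a median of 1.67 (adjusted p = 3.86e-101). ISG15 conjugation rose in 4 of 4 genes (4 adjusted over the list alone, median 1.76), with USP18 at 2.06 and HERC5 at 1.45. Nucleic acid sensors rose in 7 of 15 cases (7 adjusted over the list alone), with AIM2 at 2.02, RIGI at 1.42 and DHX58 at 1.27. Class I antigen presentation rose in 11 of 19 genes (14 adjusted over the list alone, median 0.38), with PSMB9 at 1.19 and TAP1 at 1.07. Class II genes rose in 5 of 11 cases (5 adjusted over the list alone, median 0.31), with HLA-DPA1 at 0.99, HLA-DQA1 at 0.99 and CD74 at 0.79, each on the brightest probe set alone. Cell death genes rose in 3 of 18 cases (8 adjusted over the list alone), with MLKL at 0.74. Among the GAS-type and GBP genes 3 of 17 rose (6 adjusted over the list alone, adjusted p = 0.00488, or 0.0788 with an estimated correlation), with APOL1 at 0.47. GBP1 at 0.49 turned to -0.12 when probe sets ending in _x_at or _s_at were left out. Macrophage markers had a median of 0.35 (5 of 15 rose, 10 adjusted over the list alone, adjusted p = 0.0854 with an estimated correlation), with C1QB at 0.62 and C1QC at 0.65 (adjusted p = 0.00999, or 0.0562 without untreated replicate 1 and 0.0537 with the axis score as a covariate). Hepatic transporters (median -0.15, 1 of 18 fell, 2 adjusted over the list alone) and drug and bile acid metabolism (median -0.0725, 1 of 24 fell, 5 adjusted over the list alone) were not called with an estimated correlation (adjusted p = 0.249 and 0.427).

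**Figure D2:**
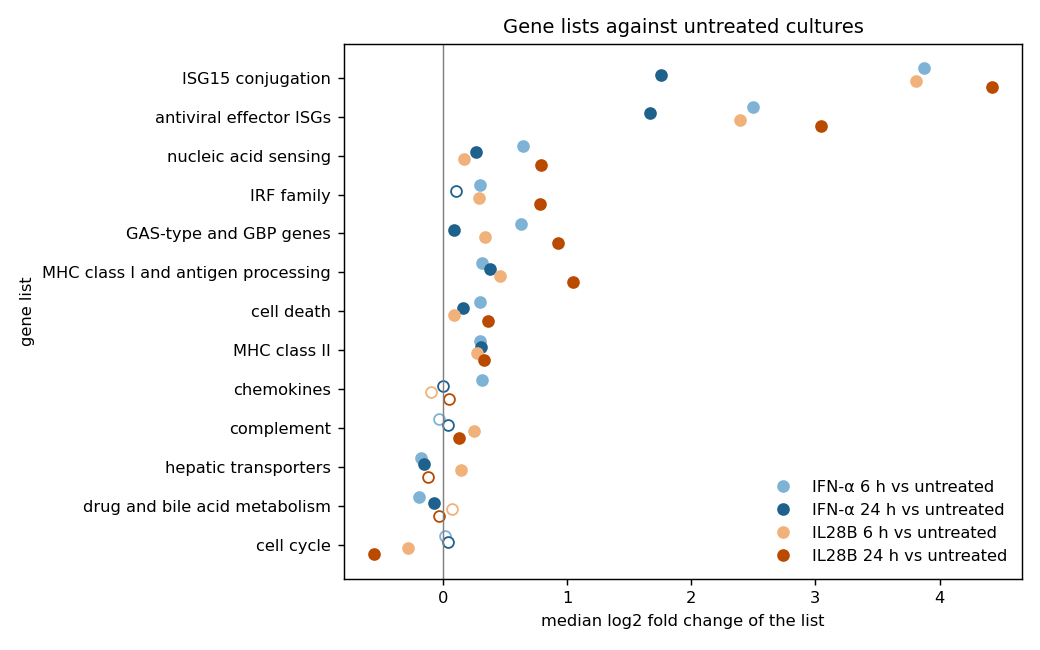
Median log2 fold change against untreated cultures of 13 gene lists (vertical axis) for each agent and time, with filled points where the list test passed an adjusted p under 0.05 with the preset correlation and open points where it did not. The antiviral effectors had medians of 2.49 and 1.67 with IFN-α and 2.39 and 3.05 with IL28B at 6 and 24 h, and the cell cycle list fell only with IL28B.

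The second question was which genes a type III interferon changed in the same cells. After 6 h of IL28B, IFI44L rose by 6.73 ± 0.16, RSAD2 by 6.36 ± 0.0941 and CXCL10 by 6.13 ± 0.15 (log2 ± SE, n = 3 arrays per group, adjusted p of at most 3.39e-13), against untreated cells at 6.68 ± 0.0281 (SD) for RSAD2. EPSTI1, IFIT1, OASL, IFI44, CMPK2, the transcription factor gene ETV7 and HERC5 followed, from 4.596 down to 3.95. TGFB2 fell by 1.68 ± 0.10, MAP1B by 1.55 ± 0.10 and FGF2 by 1.46 ± 0.15 (adjusted p of at most 1.46e-05). GPATCH11 fell by 1.68 ± 0.11, again on the brightest probe set alone. OSBPL10 fell by 1.44, but its other 4 probe sets were not called and its value turned to 0.0381 without the _x_at and _s_at probe sets. IFNLR1, which encodes the specific chain of the IL28B receptor, rose by 0.69 ± 0.17 (adjusted p = 0.0248). Leaving out untreated replicate 2 or 3 or IL28B 6 h replicate 2 or 3 ended that call (0.0682 to 0.0911), and its other probe set gave 0.17. CXCL11 rose by 0.78 ± 0.21 (adjusted p = 0.0303), a call lost without untreated replicate 2 or 3 or IL28B 6 h replicate 1 or 3 (0.0542 to 0.125), in a fit of the compared groups alone (0.0717) or with the axis score as a covariate (0.164), and its other probe set gave 0.0794, not called. SOCS1 rose by 1.27 ± 0.14, while CXCL9 at 0.12 ± 0.17 was not called. IL28B at 6 h changed 1847 genes (963 rose and 884 fell), with 139 and 39 by 2-fold or more. That count fell to 728 and 783 without untreated replicates 2 and 3, and to 1174 and 1218 without IL28B 6 h replicates 1 and 2. It came to 3215 without the 2 arrays that stood apart, which belong to other groups, to 3387 with array weights and to 963 with the axis score as a covariate. Over the brighter genes outside the lists, the changes correlated at r = 0.50 with the deviation of IFN-α 24 h replicate 2 from its group. Genes that rose made up 52.1%, or from 48.0% with quantile normalization to 62.2% without untreated replicate 3.

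Of the antiviral effectors, 44 of 46 rose with IL28B at 6 h (45 adjusted over the list alone), with a median of 2.39 (adjusted p = 1.13e-98). ISG15 conjugation rose in 4 of 4 genes (4 adjusted over the list alone, median 3.81), with USP18 at 3.77 and ISG15 at 3.85. Nucleic acid sensors rose in 7 of 15 cases (7 adjusted over the list alone), with RIGI at 2.63, IFIH1 at 2.36 and DHX58 at 2.19. Of the interferon regulatory factors 2 of 7 rose (3 adjusted over the list alone), IRF7 by 2.49 and IRF1 by 1.35. Class I antigen presentation rose in 14 of 19 genes (14 adjusted over the list alone, median 0.46), with NLRC5 at 2.11, TAP1 at 1.99 and PSMB9 at 1.798. GAS-type and GBP genes rose in 11 of 17 cases (13 adjusted over the list alone), with GBP4 at 3.18 and APOL3 at 1.47, and cell death genes in 2 of 18 (4 adjusted over the list alone), with MLKL at 2.40 and TNFSF10 at 2.06. Cell cycle genes fell in 9 of 22 cases (9 adjusted over the list alone, median -0.28, adjusted p = 5.50e-06), with AURKA at -0.52 (adjusted p = 0.101 without the _x_at and _s_at probe sets) and MCM4 at -0.58, the latter on 1 of its 5 probe sets. The chemokine list had no common direction (median -0.10, adjusted p = 0.702): 5 rose and 3 fell (7 and 5 adjusted over the list alone), with the liver chemokine CCL16 at 0.95. Complement genes (median 0.25, 6 of 17 rose, 9 adjusted over the list alone, adjusted p = 0.23 with an estimated correlation) included C6 at 0.53 and C1R at 0.49. Class II genes (median 0.28, 2 of 11 rose, 4 adjusted over the list alone), hepatic transporters (median 0.15, 3 rose and 1 fell, 5 and 1 adjusted over the list alone) and macrophage markers (median 0.22, 4 of 15 rose, 6 adjusted over the list alone) also passed only with the preset correlation (adjusted p = 0.182, 0.372 and 0.301 with an estimated correlation).

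IL28B for 24 h gave the largest response in the series. With folds that are not exact for IFI44L, CXCL10, MX2, OR52K3P and CXCL11, IFI44L rose by 8.63 ± 0.16 and CXCL10 by 8.61 ± 0.15 (log2 ± SE, n = 3 arrays per group, adjusted p = 1.69e-14 and 9.38e-15), the latter from 3.98 ± 0.34 to 12.59 ± 0.13 (SD). RSAD2, ETV7, MX2 and EPSTI1 rose by 6.95, 5.26, 5.25 and 5.24. The pseudogene OR52K3P rose by 5.08 ± 0.15, SAMD9L by 4.94, OASL by 4.86 and IFIT1 by 4.85. CXCL11 rose by 4.49 ± 0.21 (adjusted p = 5.36e-10), and 1.59 on its other probe set. CYP7A1, the gene of the rate-limiting enzyme of bile acid synthesis, fell by 2.49 ± 0.32 (adjusted p = 5.92e-05). LINC01963, NANOS1, the iron-sulfur protein gene ACO1 and GPATCH11 fell by 2.35, 2.13, 2.05 and 2.02, and the other probe sets of ACO1 and GPATCH11 fell by 1.35 and 0.54. IFNLR1 rose by 1.21 ± 0.17 (adjusted p = 1.60e-04) on its brightest probe set and by 0.0469, not called, on the other. IFNAR1 fell by 0.61 ± 0.0929, while of its 3 other probe sets 1 fell and 2 were not called (0.25 on the farthest). IFNAR2 rose by 0.49 ± 0.0963 on 1 of its 3 probe sets (0.0505 on the farthest other), SOCS1 rose by 1.996 ± 0.14, and IL10RB and CXCL9 at 0.19 and 0.24 were not called. In all, 4317 genes changed (1850 rose and 2467 fell), with 320 and 199 by 2-fold or more. The count was 2837 without IL28B 24 h replicate 3 and 2786 with the axis score as a covariate. The changes correlated at r = 0.45 with the deviation of IFN-α 24 h replicate 2, as described for 6 h. The share of higher genes was 42.9%, or from 40.6% without the _x_at and _s_at probe sets to 51.1% with each array centred on its median, so the excess of decreases was not firm.

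**Figure D3:**
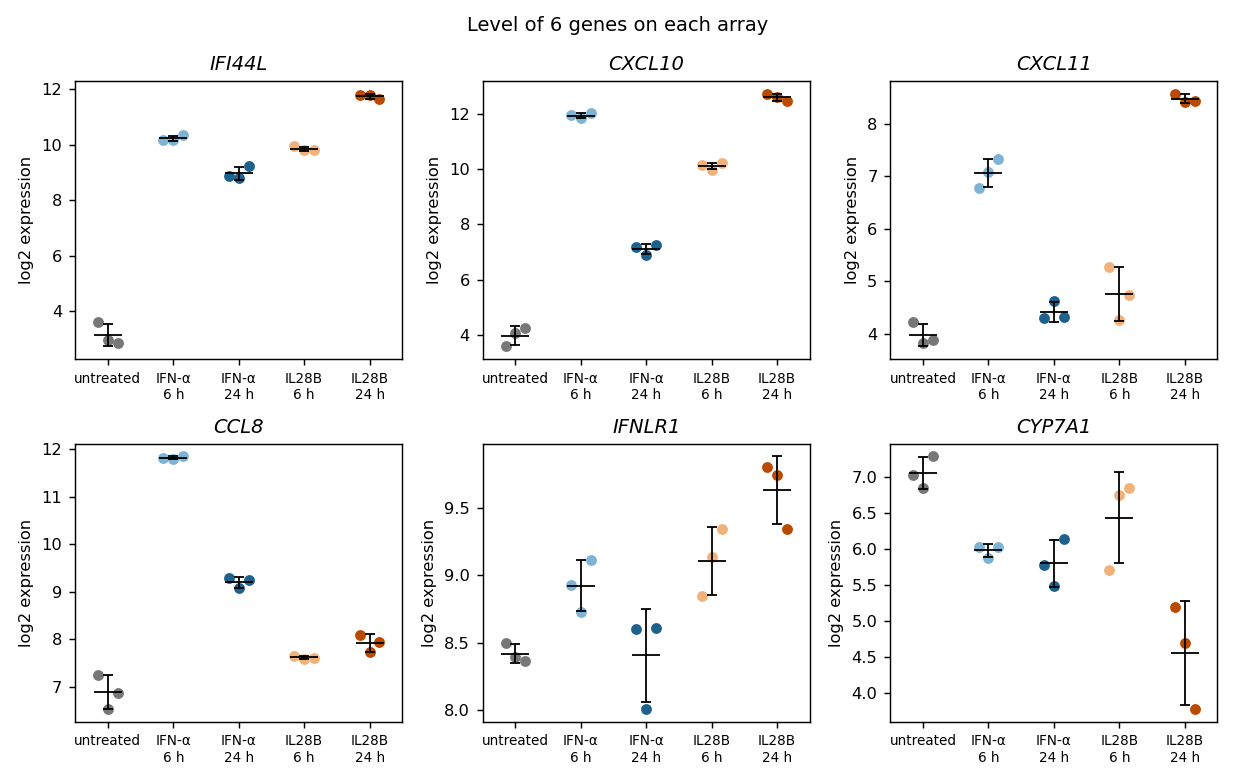
Level (log2 expression, vertical axes) of 6 genes on each array by group, with points for arrays and bars for the mean and SD of 3 arrays. CXCL10 reached 11.93 ± 0.0945 after 6 h of IFN-α and 12.59 ± 0.13 after 24 h of IL28B, and CCL8 rose to 11.83 ± 0.0273 with IFN-α at 6 h against 7.62 ± 0.0301 with IL28B.

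All 46 measured antiviral effectors rose after 24 h of IL28B (46 adjusted over the list alone), with a median of 3.05 (adjusted p = 7.53e-81). ISG15 conjugation rose in 4 of 4 genes (4 adjusted over the list alone, median 4.42). Class I antigen presentation rose in 16 of 19 genes (16 adjusted over the list alone, median 1.05), with PSMB9 at 2.61, NLRC5 at 2.52 and TAP1 at 2.32. Nucleic acid sensors rose in 9 of 15 cases (10 adjusted over the list alone), with IFI16 at 3.19 and DHX58 at 2.997. Interferon regulatory factors rose in 4 of 7 cases (4 adjusted over the list alone), with IRF7 at 3.11 and IRF3 at 0.92. GAS-type and GBP genes rose in 12 of 17 (13 adjusted over the list alone), with GBP4 at 3.81, and cell death genes in 9 of 18 (12 rose and 1 fell adjusted over the list alone), with MLKL at 2.81 and TNFSF10 at 2.79. Cell cycle genes fell in 14 of 22 cases (14 adjusted over the list alone, median -0.55, adjusted p = 8.27e-08), with TOP2A at -0.95, TYMS at -0.91 and MCM2 at -0.90. The farthest other probe sets of TOP2A and TYMS gave -0.104 and -0.0147. Of the chemokines 4 rose and 4 fell (4 and 4 adjusted over the list alone, median 0.0487, adjusted p = 0.353), with CX3CL1 at 1.98. The called lists among these held with an estimated correlation.

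Among liver genes at 24 h of IL28B, the lectin gene MBL2 fell by 1.68 and the complement gene C9 by 1.06, while C1R rose by 0.80. The complement list had 6 risen and 2 fallen members of 17 (6 and 2 adjusted over the list alone, median 0.13, adjusted p = 0.596 with an estimated correlation). Cholesterol and fatty acid synthesis rose in 7 of 18 genes (8 rose and 1 fell adjusted over the list alone, median 0.15), with MVD at 0.86 and DHCR7 at 0.67, but the list was not called with an estimated correlation (adjusted p = 0.487). Of the secretory proteins and regulators 5 rose and 1 fell of 23 (7 and 1 adjusted over the list alone, median 0.19, adjusted p = 0.595 with an estimated correlation), with NR0B2 at 0.68 and FOXA3 at 0.63. Class II genes (median 0.33, 5 of 11 rose, 6 adjusted over the list alone, with CD74 at 1.01 on its brightest probe set alone) and macrophage markers (median 0.22, 3 of 15 rose, 3 adjusted over the list alone, with CD14 at 0.89, or 0.42 and not called with the axis score as a covariate) passed with the preset correlation only (adjusted p = 0.168 and 0.487 with an estimated correlation).

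The overlap of the responses to both agents was compared with chance, since both used the same untreated arrays. At 6 h, 316 genes rose and 27 fell with both agents, against 24.5 and 4.21 for independent lists. At 24 h, 277 rose and 90 fell with both, against 33.6 and 13.5, and the 90 became 59 with the mean of a gene's probe sets. Part of this excess over independent lists may come from the shared controls, since 3 control arrays cannot be split into parts of at least 2. Of the genes that rose with IFN-α, 62.9% also rose with IL28B at 6 h and 77.4% at 24 h, while of those that rose with IL28B 32.8% and 14.97% also rose with IFN-α. The log2 fold changes of the 2 agents correlated across genes at r = 0.60 at 6 h and 0.72 at 24 h, against 0.50 in 100 simulations of unchanged groups. The covariance was 0.0570 and 0.0789, against 0.0103 simulated. The simulated noise was independent between genes, unlike that of the arrays, so it cannot show how far these values stray without a response. Of the genes that rose with IFN-α at 6 h, 4 fell with IL28B, namely CHIC2, CHN1, EMP1 and MYOF, which were chosen after their values were seen. MYOF rose by 0.70 ± 0.15 with IFN-α (SE, adjusted p = 0.0156) and fell by 1.15 ± 0.15 with IL28B (adjusted p = 2.13e-04). Its rise was not called without untreated replicate 1 or 2 or IFN-α 6 h replicate 3 (adjusted p of at most 0.0987). The fall of CHIC2 ended without any untreated array, IFN-α 24 h replicate 1, IFN-α 6 h replicate 1 or IL28B 6 h replicate 2 or 3, and that of CHN1 without untreated replicate 1 or 3, IFN-α 6 h replicate 1 or any IL28B 6 h array (adjusted p of at most 0.14 and 0.155). The rise of EMP1 ended without any untreated array or IFN-α 6 h replicate 1 or 3, and its fall without any untreated array or IL28B 6 h replicate 2 or 3 (at most 0.151 and 0.112). At 24 h the genes that rose with IFN-α and fell with IL28B were ABTB3 and SRPX2. Their rises ended without any untreated or IFN-α 24 h array, IFN-α 6 h replicate 3 or IL28B 24 h replicate 2, for ABTB3 also IFN-α 6 h replicate 2 or IL28B 6 h replicate 3 and for SRPX2 also IFN-α 6 h replicate 1 or IL28B 6 h replicate 2 (at most 0.14 and 0.171). Both rises also ended with each array centred on its median (adjusted p = 0.0765 and 0.0679). The fall of SRPX2 ended without any untreated array or IL28B 24 h replicate 1 or 2 (at most 0.127).

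Other genes, chosen after their values were seen, fell with IFN-α and rose with IL28B: CYP2D6 and SERPINA10 at 6 h, and N4BP2L1 and PCK1 at 24 h. With IL28B they rose by 0.74 ± 0.13, 0.34 ± 0.074, 0.38 ± 0.11 and 1.03 ± 0.14 (log2 ± SE, n = 3 arrays per group, adjusted p = 0.00239, 0.0103, 0.0198 and 1.34e-04). The fall of CYP2D6 with IFN-α ended without any array except untreated replicate 2, IFN-α 24 h replicate 2 and IL28B 24 h replicates 2 and 3, and that of N4BP2L1 without any array except IL28B 6 h replicates 1 and 3 and IL28B 24 h replicate 3 (adjusted p of at most 0.203 and 0.207). That of SERPINA10 ended without any untreated or IFN-α 6 h array (at most 0.115), and that of PCK1 without untreated replicate 1 or 2 or IFN-α 24 h replicate 1 (at most 0.0567). The rise of SERPINA10 ended without untreated replicate 3 (0.0528), and that of N4BP2L1 without untreated replicate 2 or 3 or IL28B 24 h replicate 1 or 2 (at most 0.0699).

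The third question was how the agents differed at the same time, at 1 dose of each in different units. At 6 h, CCL8 was higher with IFN-α than with IL28B by 4.21 ± 0.14 (log2 ± SE, n = 3 arrays per group, adjusted p = 4.74e-10), the DNA sensor gene AIM2 by 3.42 ± 0.23, CXCL11 by 2.30 ± 0.21 (0.537, not called, on its other probe set) and the transcription factor gene TFEC by 2.10 ± 0.23 (adjusted p of at most 1.17e-04). AIM2 stood at 3.43 ± 0.0968 (SD) in untreated cells and 3.52 ± 0.56 with IL28B, the 13 percentile. TFEC with IL28B lay at the 17.5 percentile, so these 2 differences are not exact. CXCL10 was higher by 1.82 ± 0.15 (adjusted p = 1.22e-05). OSBPL10, at 1.89, turned to -0.0455 without the _x_at and _s_at probe sets. Lower with IFN-α were the erythropoietin gene EPO by 1.67 ± 0.20, CYP2A6 by 1.48 ± 0.20, APOA4 by 1.48 ± 0.23, CYP2A7 by 1.34 ± 0.21 and CCL16 by 1.33 ± 0.15 (adjusted p of at most 0.00154). CYP2A6 and CYP2A7 are close paralogs, and probe sets may not separate them. Chemokines were higher in 12 of 22 and lower in 2 (13 and 2 adjusted over the list alone, median 0.59, adjusted p = 1.91e-08). With the axis score as a covariate 7 were higher and 2 lower, with a median of 0.43. Cell cycle genes were higher in 8 of 22 (11 adjusted over the list alone, median 0.26), with RRM2 at 0.67. In all 1732 genes differed, 809 higher and 923 lower with IFN-α, with 86 and 24 of them by 2-fold or more. The count was 737 and 609 without IFN-α 6 h replicates 1 and 3, 832 without IL28B 6 h replicate 2, 937 with the axis score as a covariate, 3039 without the 2 arrays that stood apart and 3703 with array weights. Genes higher with IFN-α made up 46.7%, or from 38.6% with each array centred on its median to 55.2% without IFN-α 6 h replicate 3.

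The antiviral effectors were close between the agents at 6 h, with 4 of 46 higher with IFN-α (4 adjusted over the list alone) and a median of 0.12 (adjusted p = 5.63e-04, or 0.152 with an estimated correlation), which became 0.0350 with the axis score as a covariate. The exceptions were MX2 at 1.38, SAMD9L at 1.02, LAMP3 at 0.70 and SAMD9 at 0.68, the last chosen after its value was seen. Nucleic acid sensors (median 0.18, 2 of 15 higher, 3 adjusted over the list alone) and cell death genes (median 0.17, 5 of 18 higher, 6 higher and 1 lower adjusted over the list alone, with CASP1 at 0.70) held with an estimated correlation. GAS-type and GBP genes did not (median 0.19, 4 of 17 higher, 8 higher and 1 lower adjusted over the list alone, adjusted p = 0.129 with an estimated correlation). Liver lists were lower with IFN-α: hepatic transporters (median -0.37, 10 of 18 lower, 1 higher and 10 lower adjusted over the list alone, with ABCG5 at -0.66), complement (-0.20, 6 of 17, 8 adjusted over the list alone, with C6 at -0.72) and drug and bile acid metabolism (-0.28, 10 of 24 lower and 2 higher, 12 and 2 adjusted over the list alone). With an estimated correlation none of those 3 was called (adjusted p = 0.119, 0.176 and 0.287). Over the brighter genes outside the lists, the differences between the agents at 6 h correlated at r = -0.59 with the deviation of IFN-α 24 h replicate 2, an array of neither group, from its own group. With the axis score as a covariate, the 3 medians were -0.44, -0.27 and -0.28, with 8, 2 and 7 members lower. CYP2D6 at -1.24 and NR1I3 at -1.17 rested on 1 probe set of 2 each. Secretory proteins (median -0.0744, 4 of 23 lower, 5 adjusted over the list alone, with PLG at -0.70), cholesterol and fatty acid synthesis (-0.21, 4 of 18 lower, 1 higher and 8 lower adjusted over the list alone) and cholangiocyte markers (0.32, none called, 1 higher adjusted over the list alone) were likewise lost (adjusted p = 0.426, 0.426 and 0.287 with an estimated correlation). With the axis score as a covariate 1 secretory gene and 1 gene of cholesterol and fatty acid synthesis were lower. In that fit 2 cholangiocyte markers were higher.

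At 24 h the antiviral effectors, CXCL10 and CXCL11 were lower with IFN-α than with IL28B. CXCL10 stood at -5.48 ± 0.15 and CXCL11 at -4.05 ± 0.21 (log2 ± SE, n = 3 arrays per group, adjusted p = 9.27e-12 and 5.84e-09), and -1.54 on the other probe set of CXCL11. The chemokine list was not called (median 0.10, 2 of 22 higher and 3 lower, 4 and 4 adjusted over the list alone, adjusted p = 0.697). BCL2L14, OR52K3P and MAB21L2 were lower by 3.75 ± 0.14, 3.72 ± 0.15 and 3.64 ± 0.10, and the other 5 probe sets of BCL2L14 were not called. The mitotic gene DLGAP5 was higher by 1.82 ± 0.22, LINC00862 by 1.82 ± 0.16, PLCE1 by 1.77 ± 0.14 and SMKR1 by 1.67 ± 0.15 (adjusted p of at most 4.67e-05), as was ABTB3 on 1 of 2 probe sets (1.71). DLGAP5 lay at the 14 percentile with IL28B, so its difference is not exact. The antiviral effectors were lower in 45 of 46 (45 adjusted over the list alone), with a median of -1.13 (adjusted p = 7.88e-69). The exception, IFITM3, was chosen after its value of -0.10 was seen. HERC5 stood at -3.11, IFI44L at -2.79, USP18 at -2.23 and SOCS1 at -1.93. IFNLR1 was lower by 1.23 ± 0.17 on its brightest probe set, and -0.0842 on the other. IFNAR1 was higher by 0.32 ± 0.0929 on 2 of its 4 probe sets (adjusted p = 0.0405), a call lost without any single array except the 3 of IL28B 6 h and IL28B 24 h replicate 2 (0.0534 to 0.157). It was also lost in a fit of the compared groups alone (0.144), with each array centred on its median (0.163) or without the 2 arrays that stood apart (0.171). The replicate block (0.0609), the mean of its probe sets (0.0703), quantile normalization (0.0501) and leaving out _x_at and _s_at probe sets (0.0517) ended it too. In all 2240 genes differed, 1311 higher and 929 lower, with 91 and 195 of them by 2-fold or more, and the count lay between 1534 and 2436 without single arrays. The share of higher genes was 58.5%, or from 38.5% with each array centred on its median to 61.5% without the dimmer genes, and the count was 3495 with the axis score as a covariate, 4224 with array weights and 1078 (49.6% higher) in a fit of the compared groups alone.

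Other lists at 24 h of both agents were lower with IFN-α in 12 of 19 class I genes (15 adjusted over the list alone, median -0.53), 12 of 17 GAS-type and GBP genes (13 adjusted over the list alone, median -0.48), 4 of 4 ISG15 conjugation genes (4 adjusted over the list alone, median -1.54) and 6 of 18 cell death genes (1 higher and 6 lower adjusted over the list alone, median -0.24). NLRC5 stood at -1.65, GBP4 at -3.61 and TNFSF10 at -2.30. Nucleic acid sensors were lower in 9 of 15 and higher in 1, AIM2, at 1.51, chosen after its value was seen and not exact, since AIM2 lay at the 18.1 percentile with IL28B (9 and 2 adjusted over the list alone, median -0.70), with IFI16 at -2.13 and TLR3 at -1.70. Interferon regulatory factors (median -0.59, 3 of 7 lower, 4 adjusted over the list alone, with IRF1 at -1.33) and NF-κB targets (median -0.0771, 5 of 18 lower, 5 adjusted over the list alone, with IL15 at -0.65) were also lower. Cell cycle genes were higher with IFN-α in 12 of 22 (14 adjusted over the list alone, median 0.49, adjusted p = 6.43e-10), with TOP2A at 1.21 (-0.0132 on its farthest other probe set), CCNB1 at 1.12 and CDC20 at 0.96. Complement (median -0.18, 4 of 17 lower and 1 higher, 6 and 1 adjusted over the list alone, with MBL2 at 1.13), secretory proteins (-0.14, 3 of 23 lower, 3 adjusted over the list alone) and cholesterol and fatty acid synthesis (-0.17, 6 of 18 lower and 1 higher, 6 and 1 adjusted over the list alone) were not called with an estimated correlation (adjusted p = 0.364, 0.363 and 0.362).

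The fourth question was how each response changed between 6 and 24 h. No untreated arrays are matched to these times, so time in culture was not separated from the response within either agent. With IFN-α, CXCL10 fell by 4.82 ± 0.15, GBP4 by 3.36 ± 0.0892, MAB21L2 by 2.80 ± 0.10 and HERC5 by 2.65 ± 0.12 (log2 ± SE, n = 3 arrays per group, adjusted p of at most 6.37e-09), against untreated cells at 7.32 ± 0.0293 (SD) for HERC5. The immune checkpoint gene CD274 fell by 2.91 ± 0.20 (adjusted p = 2.57e-07), and by 0.84, not called, on its other probe set. HCP5 rose by 1.51 ± 0.13, IFI27 by 1.25 ± 0.0836 and, on 1 of its probe sets each, GPATCH11 and LILRA2 by 1.23 and 1.03. EPO rose by 0.95 (adjusted p = 0.0135, or 0.0847 without IFN-α 6 h replicate 3, 0.0741 without IFN-α 24 h replicate 2 and 0.0507 with the axis score as a covariate). Antiviral effectors fell in 33 of 46 and rose in 2, IFI27 and BST2 (36 and 3 adjusted over the list alone, median -0.67, adjusted p = 5.49e-43), with RTP4 at -2.11. BST2, chosen after its value was seen, rose by 0.53, a call lost without IFN-α 24 h replicate 2 or IFN-α 6 h replicate 1 or 3 (adjusted p of at most 0.121). Chemokines fell in 7 of 22 (11 adjusted over the list alone, median -0.29), among them CXCL11 and CCL8 by 2.64 and 2.63, while the other probe set of CXCL11 gave -0.567 and was not called. In all 757 genes changed, 341 higher and 416 lower at 24 h, with 4 and 108 of them by 2-fold or more. The count was 365 and 321 without IFN-α 6 h replicates 1 and 3, 463 and 377 without IFN-α 24 h replicates 1 and 2, 478 with the axis score as a covariate, 460 without the 2 arrays that stood apart, 321 in a fit of the compared groups alone and 4127 with array weights. The share of higher genes was 45.0%, or 21.8% with the compared groups alone and 63.4% with array weights.

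Further lists fell between 6 and 24 h of IFN-α: nucleic acid sensors (8 of 15, 9 adjusted over the list alone, median -0.39), GAS-type and GBP genes (9 of 17, 11 adjusted over the list alone, -0.51), ISG15 conjugation (2 of 4, 3 adjusted over the list alone, -1.08) and interferon regulatory factors (2 of 7, 2 adjusted over the list alone, -0.33). IFIH1 fell by 1.44, TLR3 by 1.43, USP18 by 1.98 and IRF1 by 1.02. Cell death genes (6 of 18 fell, 1 rose and 9 fell adjusted over the list alone, median -0.21) included MLKL at -1.88, and NF-κB targets (2 of 18 fell, 4 adjusted over the list alone, median -0.13) included IL15 at -1.26. Interferon receptors and JAK-STAT genes (1 of 11 fell, 3 adjusted over the list alone, median -0.21) were not called with an estimated correlation (adjusted p = 0.197), though JAK2 fell by 1.54.

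**Figure D4:**
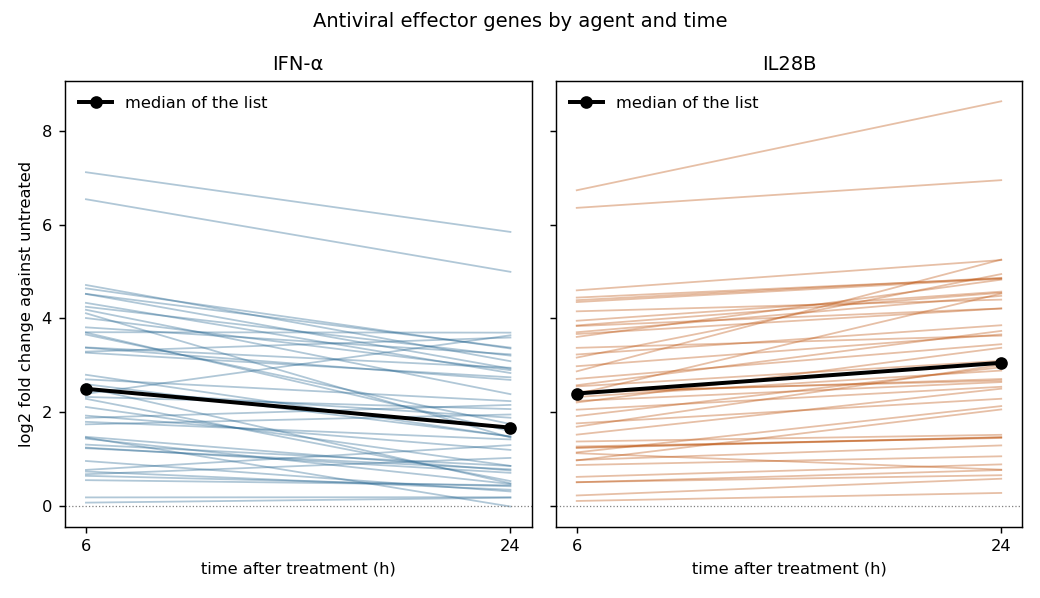
Log2 fold change against untreated cultures (vertical axis) of the 46 measured antiviral effector genes at 6 and 24 h (horizontal axis) of each agent, with 1 line per gene and the list median in black. The median went from 2.49 to 1.67 with IFN-α and from 2.39 to 3.05 with IL28B.

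Between 6 and 24 h of IL28B, CXCL11 rose by 3.71 ± 0.21 (1.51 on its other probe set), CXCL10 by 2.48 ± 0.15, MX2 by 2.39 ± 0.14 and IFI27 by 2.15 ± 0.0836 (log2 ± SE, n = 3 arrays per group, adjusted p of at most 1.86e-07), with IFI27 at 8.54 ± 0.0806 (SD) in untreated cells. The hexokinase gene HK2 rose by 2.01 ± 0.18, on 1 of 3 probe sets. CYP7A1 fell by 1.87 ± 0.32 (adjusted p = 0.00279), DANCR by 1.83 ± 0.0874, LINC01963 by 1.83 ± 0.21 and ACO1 by 1.70 ± 0.11, and MTURN by 1.47 on 1 of 2 probe sets. Antiviral effectors rose in 30 of 46 (40 rose and 1 fell adjusted over the list alone, median 0.53, adjusted p = 1.12e-39). Acute phase genes fell in 3 of 15 (5 fell and 1 rose adjusted over the list alone, median -0.0727): CRP by 1.16, FGA by 0.91 and FGG by 0.76 (adjusted p of at most 1.63e-05), although the list was not called with an estimated correlation (0.091). In all 1152 genes changed, 528 higher and 624 lower at 24 h, with 56 and 28 of them by 2-fold or more. The count was 753 without IL28B 6 h replicate 3, 760 without IL28B 24 h replicate 2, 353 in a fit of the compared groups alone and 2249 with the axis score as a covariate. The share of higher genes was 45.8%, or from 42.5% without the dimmer genes to 57.5% with each array centred on its median.

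Class I antigen presentation rose between 6 and 24 h of IL28B in 9 of 19 genes (15 adjusted over the list alone, median 0.34), with PSMB9 at 0.81 and HLA-E at 0.74. Nucleic acid sensors rose in 6 of 15 (7 adjusted over the list alone, 0.27), GAS-type and GBP genes in 9 of 17 (10 adjusted over the list alone, 0.36), ISG15 conjugation in 4 of 4 (4 adjusted over the list alone, 0.57) and cell death genes in 6 of 18 (8 rose and 1 fell adjusted over the list alone, 0.27). IFI16 rose by 1.20, GBP3 by 0.63, ISG15 by 0.70 and CASP1 by 0.92 (adjusted p = 0.0956 without the _x_at and _s_at probe sets). Cell cycle genes (7 of 22 fell, 8 adjusted over the list alone, median -0.28) and hepatic transporters (6 of 18 fell, 10 adjusted over the list alone, median -0.33) were not called with an estimated correlation (adjusted p = 0.0582 and 0.0582), with SLC22A9 at -0.94 and ABCG2 at -0.51. Drug and bile acid metabolism (5 of 24 fell, 6 adjusted over the list alone, median -0.052, with CYP2E1 at -0.87), cholesterol and fatty acid synthesis (none called and 0 adjusted over the list alone, 0.19) and stress responses (1 of 26 rose, 4 adjusted over the list alone, 0.0703) were lost as well (adjusted p = 0.347, 0.285 and 0.173 with an estimated correlation).

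The difference between the time courses was tested as an interaction, the change from 6 to 24 h with IFN-α minus that with IL28B. It stood at -7.30 ± 0.21 for CXCL10 and -6.35 ± 0.29 for CXCL11 (log2 ± SE, n = 3 arrays per group, adjusted p = 4.34e-11 and 6.31e-09). From 6 to 24 h the other probe set of CXCL11 gave -0.567, not called, with IFN-α and 1.51 with IL28B. The difference for CXCL11 was thus smaller on that probe set. The antiviral effectors had a median interaction of -1.19, with 42 of 46 more negative with IFN-α (45 adjusted over the list alone, adjusted p = 7.68e-83). GPATCH11 and ACO1 went the other way, at 1.57 ± 0.15 and 1.35 ± 0.16, although ACO1 turned to -0.16 without the _x_at and _s_at probe sets. In all 811 genes had an interaction, 327 positive and 484 negative, with 24 and 239 of them by 2-fold or more. The count lay between 563 and 1017 without single arrays and was 1919 with array weights. The share of positive interactions was 40.3%, or from 29.1% with each array centred on its median to 56.1% with array weights.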

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

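The tests of another share of nonparenchymal cells, lower oxygen, unequal doses, a faster loss of IFN-α and more myeloid cells were chosen only after the results were seen. No single array was tested against its group.

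The time course differed between the agents in 811 genes, by the interaction of agent and time. All values here are the log2 change from 6 to 24 h with IFN-α minus that with IL28B, on each gene's brightest probe set. The interactions of the other probe sets were not compared with these, and that of CXCL11 was smaller on its other probe set. The chemokine genes CXCL10 and CXCL11 had the most negative values, -7.30 and -6.35, with CCL8 at -2.93 and CXCL9 at -0.93. Antiviral genes followed: SAMD9L (-3.58), MX2 (-3.43), HERC5 (-3.27), USP18 (-2.50), ISG15 (-0.71). The sensors were IFI16 (-2.58), TLR3 (-2.06), IFIH1 (-1.95), and the guanylate-binding proteins GBP4 (-3.98), GBP5 (-1.78). Antigen presentation was represented by NLRC5 (-1.89), TAP2 (-1.77), PSMB9 (-1.46), cell death by MLKL (-2.29), TNFSF10 (-2.24), CASP1 (-1.43), and the pseudogene OR52K3P and BCL2L14 stood at -4.60 and -4.11. Signalling genes were IFNLR1 (-1.04), SOCS1 (-1.50), JAK2 (-2.34), IRF2 (-1.33), IRF1 (-1.09), IRF7 (-0.95), inflammatory genes IL15 (-1.30), TNFAIP3 (-1.02), TLR2 (-0.84), and MUC1 stood at -0.97. Positive values were those of GPATCH11 (1.57), ACO1 (1.35), LRFN5 (1.30), LINC01963 (1.29), DNAH5 (1.25) and of the liver genes CRP (0.83), FGA (0.77), FGG (0.57), CYP2A6 (1.14), CYP2E1 (0.66), SLC22A9 (1.03), ABCG5 (0.58).

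Some of these calls ended when 1 array was left out. IRF7 lost its call without any array except IFN-α 24 h replicate 2, IL28B 6 h replicate 1 and IL28B 24 h replicate 2 (adjusted p of at most 0.108), and CXCL9 without any array except untreated replicates 1 and 3, IL28B 6 h replicate 1 and IL28B 24 h replicate 1 (at most 0.117). IFNLR1 and IRF2 lost theirs without IFN-α 6 h replicate 1 or 3, IL28B 6 h replicate 1 or 2, or IL28B 24 h replicate 1 or 2 (at most 0.0792 and 0.0855). CYP2A6 lost its call without any of the same arrays except IL28B 6 h replicate 1, and without IFN-α 24 h replicate 1 or 2 or IL28B 6 h replicate 3 (at most 0.0994). LINC01963 lost its call without IFN-α 6 h replicate 3, IFN-α 24 h replicate 1 or 2 or IL28B 6 h replicate 2 (at most 0.0626), and ISG15 without IFN-α 6 h replicate 2 or IFN-α 24 h replicate 1 or 3 (at most 0.0621). A fit of the compared groups alone ended the calls of IRF7, IRF2, IFNLR1 and CYP2A6 (adjusted p = 0.0856, 0.0559, 0.0550 and 0.0608), and that of BCL2L14 ended without the _x_at and _s_at probe sets (0.799). The replicate number as a block ended the calls of IRF7 and CYP2A6 (adjusted p = 0.0715 and 0.0507), and quantile normalization that of IRF7 (0.0511). Leaving out the 2 arrays that stood apart ended those of CXCL9, LINC01963 and CYP2A6 (adjusted p = 0.110, 0.0870 and 0.0638), and the mean of a gene's probe sets ended that of IFNLR1 (0.207).

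Whole lists differed in the same way. Median interactions were -1.61 for ISG15 conjugation, -1.19 for antiviral effectors, -0.88 for nucleic acid sensing, -0.78 for GAS-type and GBP genes, -0.68 for the IRF family, -0.48 for chemokines, -0.44 for cell death, -0.32 for class I antigen presentation and -0.0935 for NF-κB targets, all of which held with an estimated correlation. Interferon receptors and JAK-STAT genes (-0.12), acute phase proteins (0.19), drug and bile acid metabolism (0.27), hepatic transporters (0.35) and cholangiocyte markers (0.00456) did not hold (adjusted p from 0.176 to 0.277 with an estimated correlation). For cholangiocyte markers the median was positive while the mean of -0.26 and the test were negative, and the median turned to -0.0537 with each array centred on its median.

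The opposite time courses of the antiviral effectors were weighed against technical explanations. With the array score on the within-group axis as a covariate the list kept 0.964 of its interaction, and over single arrays left out it kept at least 0.920, which argues against that axis or 1 array as the whole cause. At 6 h the list median lay 0.12 in favour of IFN-α (0.0350 with the covariate), so the list was not induced less by IFN-α at that time. An IFN-α dose of weaker effect stays open, since 1 early time and 1 dose of each agent, in different units, cannot compare doses. A faster loss of IFN-α than of IL28B from the medium could give the fall with IFN-α (list median -0.67), and cannot be told apart from a loss of response by the cells, since no level of either agent in the medium is at hand.

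At 24 h of IL28B, 3655 genes were called that were not called with IFN-α at either time, with a median absolute change of 0.51, and 1312 of them (35.9%) differed between the agents at 24 h. With the within-group axis as a covariate the median ratio of adjusted to unadjusted change was 0.709 (0.659 to 0.813 with single arrays left out), and 1579 genes (43.2%) were still called, so the axis cannot be told apart from treatment for part of these changes, because the treated groups differ along it. Another share of nonparenchymal cells stays open, since a change in 1 cell type would move its own markers alone: the list medians were 0.218 for macrophages (SD over members 0.252, with CD14 at 0.89), 0.157 for cholangiocytes (0.473), 0.0763 for stellate cells (0.508) and -0.10 for endothelium (0.266). Lower oxygen in the IL28B wells stays open as well, since 22 hypoxia targets, none of which is in a fixed list, had a median of -0.0448 with an SD of 0.471 over members that went both ways, and the list was called between 6 and 24 h of IL28B (adjusted p = 0.0267, or 0.23 with an estimated correlation). Among genes chosen after their values were seen, PFKFB4, ANKRD37 and ADM of that list rose by 1.68 ± 0.16, 0.92 ± 0.0866 and 0.62 ± 0.0903, BNIP3L fell by 0.33 ± 0.0871 (a call lost without untreated replicate 3, adjusted p = 0.0654), and EPO, outside it, rose by 1.08 ± 0.20 (SE), and an effect of IL28B itself and time in culture stay open, untested.

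CCL8, AIM2 and other genes were higher with IFN-α than with IL28B at 6 h, and myeloid cells in the cultures that answer IFN-α and not IL28B may explain part of this. In 19 measured myeloid interferon-responsive genes, a list written after CCL8 and AIM2 were seen to differ but before its own values were seen, the median difference was 0.31, with 8 genes higher, among them SIGLEC1 at 0.82, chosen after its value was seen (list adjusted p = 0.004 with an estimated correlation). A lack of answer to IL28B was not shown: 3 of 19 rose with IL28B at 6 h, though the list was not called (median -0.0227, adjusted p = 0.629), and 4 of 19 at 24 h, when it was (median 0.16, adjusted p = 0.0361, or 0.166 with an estimated correlation). Group means of SIGLEC1 were 6.34 in untreated cells and 6.95 and 7.08 with IL28B at 6 and 24 h. Those of CCL8 were 6.88, 7.62 and 7.92, so both were also higher with IL28B. AIM2 moved less at 6 h, with means of 3.43, 3.52 and 3.94. More myeloid cells in the IFN-α arrays stay open, although 15 macrophage markers gave little sign of them. Their median difference was 0.0168, or 0.11 with the axis score as a covariate, with 0 members called higher in that fit. Untreated levels of these markers ran from the 20.3 percentile for CD5L to the 80.3 for CD163. CD14, chosen after its value was seen, was lower with IFN-α, at -0.72 (adjusted p = 0.0321, or at most 0.121 without IFN-α 6 h replicate 1 or 3 or IL28B 6 h replicate 1 or 2). Of the 19 genes 1 lies above the median of untreated levels and 2 are in a fixed list, the labels name no sort that would remove such cells, and hepatocytes that answer the agents differently stay open.

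Probe sets without a single gene symbol, which no comparison used, also responded. Of 13522 such probe sets, 112 were called with IFN-α at 6 h, 110 with IFN-α at 24 h, 235 with IL28B at 6 h and 969 with IL28B at 24 h, each against untreated cells.

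Other splits of the arrays were counted for each comparison. For the 8 comparisons of 3 against 3 arrays, 1 of 10 splits, the real one, gave as many genes, and so few splits cannot give a share under 0.05. The real counts were 596, 466, 1847, 4317, 1732, 2240, 757 and 1152, and the highest of the other splits was 0, or 1 for the agents at 24 h. For the interaction, 6 of 100 splits gave at least 811 genes, the real one included. The highest other split gave 3488, several times the real count, which points to a structure of the samples: it exchanged all 3 arrays of the agents at 24 h and none at 6 h, and so measured the difference between the agents at both times. The other 4 exchanged 2 or 3 arrays at 24 h and 0 or 1 at 6 h, with 925 to 3034 genes. Such splits carry the difference between the agents into the interaction, so the count decides nothing about chance.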

How the results depend on the processing

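The 2 arrays left out together and the covariate for the within-group axis were chosen after the data were seen. Of 269 recomputed counts, 217 stayed within 1.5 times the reported one, 39 were lower and 13 higher. Of 12195 recomputed values of named genes, 11620 kept their direction and side of the threshold, 330 lost a call, 241 gained one and 4 reversed, all 4 when probe sets ending in _x_at or _s_at were left out, which changed the probe set: GBP1 with IFN-α at 24 h (-0.117), OSBPL10 with IL28B at 6 h (0.0381) and for IFN-α against IL28B at 6 h (-0.0455), and ACO1 in the interaction (-0.163). Array weights gave 1759 genes for IFN-α 6 h, 3421 for IFN-α 24 h, 3387 for IL28B 6 h, 3703 for the agents at 6 h, 4224 for the agents at 24 h, 4127 for IFN-α over time and 1919 for the interaction. The axis covariate gave 1016 for IFN-α 6 h, 274 for IFN-α 24 h, 963 for IL28B 6 h, 2786 for IL28B 24 h, 937 and 3495 for the agents at 6 and 24 h, and 478 and 2249 for IFN-α and IL28B over time. Without the 2 arrays that stood apart the counts were 266 for IFN-α 24 h, 3215 for IL28B 6 h, 3039 for the agents at 6 h and 460 for IFN-α over time. The cause of these changes was not tested. Fits of the compared groups alone, which hold fewer samples, gave 271 for IFN-α 24 h, 1078 for the agents at 24 h, 321 for IFN-α over time and 353 for IL28B over time. Leaving out the dimmer genes, so that fewer genes were tested, gave 786 for IFN-α 24 h. Single arrays left out gave 448 to 694 genes for IFN-α 6 h, 209 to 637 for IFN-α 24 h, 728 to 2364 for IL28B 6 h, 2837 to 4836 for IL28B 24 h, 609 to 2208 and 1534 to 2436 for the agents at 6 and 24 h, 321 to 926 and 753 to 1303 for IFN-α and IL28B over time, and 563 to 1017 for the interaction. With an estimated correlation the called lists fell from 16 to 9 for IFN-α 6 h, 10 to 6 for IFN-α 24 h, 13 to 8 for IL28B 24 h, 12 to 4 for the agents at 6 h, 12 to 6 for IL28B over time and 14 to 9 for the interaction. Genes lower with both agents at 24 h went from 90 to 59 with the mean of a gene's probe sets. On arrays, signal near background limits dim genes, for which small changes are not detectable.

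The replicate numbers were not treated as pairs. Of 30 pairs of arrays with the same number, 9 had deviations from the group means correlated above 0.1 (median -0.0257, from -0.490 to 0.504), and 4 of 15 arrays correlated best with their own number. With the replicate block the counts were 554, 352, 1363 and 3934 for IFN-α 6 and 24 h and IL28B 6 and 24 h, 1319 and 2009 for the agents at 6 and 24 h, 558 and 938 for IFN-α and IL28B over time, and 689 for the interaction. Genes lower with both agents fell from 27 to 17 at 6 h and from 90 to 59 at 24 h, the only counts that the block moved by over 1.5 times. Among named values it ended 12 calls, gained 1 and left 463 as they were.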

Other observations

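The genes in this paragraph and the next were chosen after their values were seen, and the test on neighbouring genes was chosen only after the result was seen. IL28B at 24 h moved chemokine genes in opposite directions. While CXCL10 and CXCL11 rose, the neutrophil chemokine genes CXCL2 and CXCL8 fell by 1.53 ± 0.17 and 1.04 ± 0.24 (log2 ± SE, n = 3 arrays per group, adjusted p = 1.29e-05 and 0.00618). CCL2 fell by 0.97 ± 0.26 (adjusted p = 0.016), a call lost without untreated replicate 2 or IL28B 24 h replicate 3 (at most 0.082). With IFN-α at 6 h, CX3CL1 and CXCL12 rose by 1.61 ± 0.13 and 1.10 ± 0.16 (adjusted p of at most 6.01e-04).

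Single stress and metabolic genes changed with IL28B at 24 h, while the stress response list was not called (adjusted p = 0.736). EGR1 rose by 0.92 ± 0.12, ATF3 by 0.52 ± 0.086 and DDIT3 by 0.49 ± 0.0897, while the antioxidant genes HMOX1, GCLM and NQO1 fell by 0.64 ± 0.13, 0.47 ± 0.11 and 0.36 ± 0.0821 (SE, n = 3 arrays per group, adjusted p of at most 0.00597). The gluconeogenic gene PCK1 rose by 1.03 ± 0.14 with IL28B (adjusted p = 1.34e-04) and fell by 0.75 ± 0.14 with IFN-α at 24 h (adjusted p = 0.0116, or at most 0.0567 without untreated replicate 1 or 2 or IFN-α 24 h replicate 1). The difference of PCK1 between the agents at 24 h was -1.78 ± 0.14 (adjusted p = 8.67e-07). NMNAT1 fell by 0.71 ± 0.083, and the sterol transporter gene NPC1L1, an entry factor of hepatitis C virus, rose by 0.65 ± 0.12 (adjusted p = 0.0018).

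Of the fixed lists, 8 were called in none of the 8 comparisons between groups. Their medians over those comparisons were -0.0454 to 0.0445, lowest adjusted p = 0.502 for interferon ligands, -0.039 to 0.0567, lowest adjusted p = 0.588 for entry and host factors of hepatitis C virus, -0.14 to 0.10, lowest adjusted p = 0.0664 for fatty acid oxidation and ketogenesis, and -0.12 to 0.0705, lowest adjusted p = 0.132 for nicotinamide and tryptophan metabolism. The same held for markers of stellate cells (-0.0624 to 0.10, lowest adjusted p = 0.403), endothelium (-0.10 to 0.0693, lowest adjusted p = 0.501), lymphocytes (-0.0687 to 0.0517, lowest adjusted p = 0.508) and plasmacytoid dendritic cells (-0.10 to 0.12, lowest adjusted p = 0.255). IFNL1 was called in no comparison and stood at 3.42 ± 0.0759 (SD) in untreated cells, the 12.1 percentile of all genes. Among the interferon ligands 1 gene, IFNA21, chosen after its value was seen, rose against untreated cells, by 0.42 ± 0.11 with IL28B at 6 h (adjusted p = 0.0254, or at most 0.121 without untreated replicate 2 or 3 or IL28B 6 h replicate 1 or 2), and its family holds near-identical genes that probe sets may not separate. The added list of myeloid interferon-responsive genes was called in 6 of the 8 comparisons, with medians of -0.20 to 0.31, lowest adjusted p = 3.89e-10 for IFN-α at 6 h against untreated cells, and in 3 with an estimated correlation. Hypoxia targets, the other added list, had medians of -0.0716 to 0.0874, lowest adjusted p = 0.0267, and were called in none with an estimated correlation. The p-values of the added lists were adjusted apart from the fixed lists, so their calls are not on the same footing.

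GPATCH11 and ACO1, which fell with IL28B at 24 h by 2.02 and 2.05, lie next to EIF2AK2, chosen after its value was seen, and RIGI, which rose by 1.29 and 2.98. A candidate explanation is that strong induction lowers the RNA of the neighbouring gene. Among 540 genes next to a gene raised by 2-fold or more, 5 fell by 2-fold or more (0.926%), against 194 of 18824 other genes that were not raised (1.03%; Fisher's exact test, two-sided, p = 1). The result gave no sign of a general effect on neighbours, and says nothing on these 2 pairs alone.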
